A study of Homo sapiens with 4 samples.

How the data were processed

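The series holds RNA-seq of 4 human cell lines of precursor-B acute lymphoblastic leukemia, grown in RPMI medium with fetal bovine serum. Per the labels' protocols, total RNA was extracted with TRI Reagent and mRNA libraries were made with a TruSeq RNA kit. A kit of this type does not mark strand, so reads of overlapping and antisense genes are not separated. Lines were grouped by the labels into t(4;11) (RS4;11 as replicate 1, SEM as replicate 2) and no t(4;11) (NALM6 as replicate 1, REH as replicate 2). The replicate numbers follow listing order only and pair no lines. The labels name no batch.

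The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, TopHat, HTSeq, DESeq and Cuffdiff and the genome build hg19, with no role, order or setting. The gene annotation, filters and the settings of DESeq and Cuffdiff are not given in the sources used here. Per the file headers, the first deposited table holds HTSeq counts per gene and line, not normalized, for 23,368 entries. It also holds the authors' DESeq normalized counts, a signal that equals the count divided by 1 size factor per line (0.991 for RS4;11, 0.651 for SEM, 0.924 for NALM6 and 1.75 for REH), and their means per group. Per the file headers, the same table gives the authors' fold change as a ratio of the control mean to the t(4;11) mean, with DESeq p-values and adjusted p-values. Of its log2 cells 865 were spoiled by a spreadsheet, so the log2 was taken from the ratio. The second deposited table, with 23,284 entries, holds the authors' Cuffdiff results: FPKM summarised over the libraries of each group. It also gives, per the file headers, the log2 fold change of control over t(4;11), a test statistic (a score), p-values and q-values. The sign of both deposited fold changes was turned so that a positive value is higher with t(4;11).

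Dates had replaced 28 symbols of the DESeq table, and 4 entries repeated a symbol; these were left out of the join by symbol, which held 23,165 genes. Coordinates are those of the Cuffdiff table in hg19, with the start counted from 1; a locus is the span that Cuffdiff grouped and can cover several neighbouring genes. Cuffdiff marked 14,203 genes as tested, 8928 as not tested, 151 as having too little data, 1 as having too much and 1 as failed. Its q-values stop at 0.00418, which 170 calls share. Genes tested in both tables numbered 14,127. Deposited calls were taken at an adjusted p or q under 0.05.

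The main test was edgeR 4.0.16 (R 4.3.3) on the deposited counts: TMM scaling, filterByExpr, glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment at 0.05. It tested 13,844 genes with 2 residual degrees of freedom (1.75 prior degrees of freedom, biological coefficient of variation 0.699). The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM used TMM-scaled library sizes. No fold change of a single gene is given against a group at 0. In single lines a floor of 3 counts corresponds to 0.0607 CPM in RS4;11, 0.0917 CPM in SEM, 0.0644 CPM in NALM6 and 0.0346 CPM in REH. Floors cover counting error only, since reads without molecular identifiers are not independent molecules. The gene with the most counts, EEF1A1, took between 1.61% and 2.07% of a library.

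For gene lists, camera (limma 3.58.1) was run with a preset correlation of 0.01 and with an estimated correlation, and fry was run beside it, with adjustment over lists. There were 34 lists with 846 members, all found in the table, and 32 had at least 3 tested genes. They cover MLL fusion targets and markers, the HOX clusters, B-lineage and other blood and stromal cell types, antigen presentation, signalling, metabolism and the cell cycle. Calls adjusted over each list alone are given beside those over all genes. Similarity of lines was measured on log2(CPM + 1). Overlap of calls was tested with Fisher's exact test, one-sided, per direction. DESeq2 1.42.0 and edgeR's exact test were alternatives, as were RLE size factors, other filters and thresholds, and leaving out each line in turn. GC content per gene, used in 1 check, was taken by symbol from annotated GRCh38 transcripts, with no coordinates carried over. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

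The tests were checked on 5 sets of simulated counts, each with 200 changed genes among 13,844. The quasi-likelihood test recovered 78.0% of genes changed 64-fold and 86.8% of those changed 256-fold. It called no gene in the real counts, so these rates cannot be carried over to them. Camera with the preset correlation called a list shifted 4-fold in 5 of 5 simulations and 1 of 152 unshifted lists, and with an estimated correlation in 0 of 5. Genes were drawn independently of each other. These rates therefore do not cover lists whose genes vary together, such as HOXA (estimated correlation 0.981) and ribosomal proteins (0.354).

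The groups, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The naming rule took the 10 largest changes each way among called genes that the other table also called, with a mean of at least 100 normalized counts and not at 0 in either group. It further took up to 2 called members per list and direction, or 2 by list order where none was called, 8 genes of MLL biology, and the 5 smallest adjusted p called by 1 deposited table alone, each way. Genes on the Y chromosome, XIST, immunoglobulin and T cell receptor segments, histones, small RNAs and genes with clone or open reading frame names were never named. Because the main test made no call, the rule was applied to the deposited DESeq calls; uncalled members were named only for lists that camera called. The 10 smallest p of the main test were added, and ties in Cuffdiff's q were broken by the mean count. These changes were made after the values were seen. The rules gave 54 genes, of which edgeR's exact test called 33, DESeq2 42, the authors' DESeq 41 and their Cuffdiff 26. Values of some named genes are not reported here. The microarray part of the study was not used here.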

Results

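RNA was sequenced from 4 human cell lines of precursor-B acute lymphoblastic leukemia, with 1 library per line. RS4;11 and SEM carry the translocation t(4;11), which fuses the histone methyltransferase gene MLL (KMT2A) to AFF1. NALM6 and REH lack it and formed the control group. Each group therefore held 2 lines (n = 2), and each line was treated as 1 replicate. The summed gene counts were 51,872,617 for RS4;11, 33,620,574 for SEM, 44,849,858 for NALM6 and 84,212,986 for REH. Between 15,451 genes (NALM6) and 17,053 genes (REH) had at least 1 count. Levels are given as library-size-scaled counts (CPM) per line or as a mean ± SD over the 2 lines of a group, and log2 fold changes are t(4;11) over control. The p-values of the gene tests measure the spread between lines of different leukemias, which includes every other difference between them. Camera compares the genes of a list with the other genes, and Fisher's exact test takes genes as its units. Their small p-values therefore do not measure how far a result would hold in other lines.

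The first comparison asked which genes differed between lines with and without t(4;11). MEIS1, a homeobox partner of HOX proteins and a known target of MLL fusions, stood at 145 ± 13.7 CPM in the t(4;11) lines and 0.111 ± 0.00567 CPM in the controls (SD, n = 2 each). CD44, a hyaluronan receptor on the cell surface, stood at 221 ± 37.3 CPM against 0.987 ± 0.760 CPM. In the other direction, MME, which encodes the common ALL antigen CD10, stood at 0.780 ± 0.412 CPM against 970.02 ± 43.9 CPM. DNTT, the template-independent DNA polymerase of V(D)J recombination, stood at 13.5 and 0.764 CPM in RS4;11 and SEM against 730.5 and 1858 CPM in NALM6 and REH. MLL and AFF1 themselves were similar in both groups, with log2 fold changes of 0.23 (SE 0.33) and 0.24 (SE 0.45). Both values turned negative without RS4;11, at -0.22 and -0.45. These counts do not separate the fused from the intact alleles.

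With 2 lines per group, edgeR's quasi-likelihood test called 0 of 13,844 genes at an adjusted p under 0.05. It gave 1668 genes an unadjusted p under 0.05, where 692.2 would be expected with no difference. Its smallest adjusted p was 0.0507, shared by MEIS1, CYBB, TCF4 and PTPRR. On the same counts edgeR's exact test called 408 genes (265 higher, 143 lower) and DESeq2 called 1603 (809 higher, 794 lower). The authors' deposited DESeq table called 288 genes (172 higher, 116 lower), and their deposited Cuffdiff table called 332 (174 higher, 158 lower). In counts simulated for this comparison over 13,844 genes, the quasi-likelihood test recovered 3.6% of genes changed 4-fold and 56.8% of those changed 16-fold. Of its simulated calls 8.16% were false, against 30.7% for the exact test and 55.2% for DESeq2. The quasi-likelihood test made calls in the simulated counts but called no gene in the real ones. The share of false calls also depends on how many genes were set to change in the simulation. These rates of recovery and of false calls therefore cannot be carried over to the real calls of any of these tests. Because the quasi-likelihood test made no call in the real counts, the genes named below were taken mainly from the deposited DESeq calls. This choice was made after the values were seen.

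**Figure D1:**
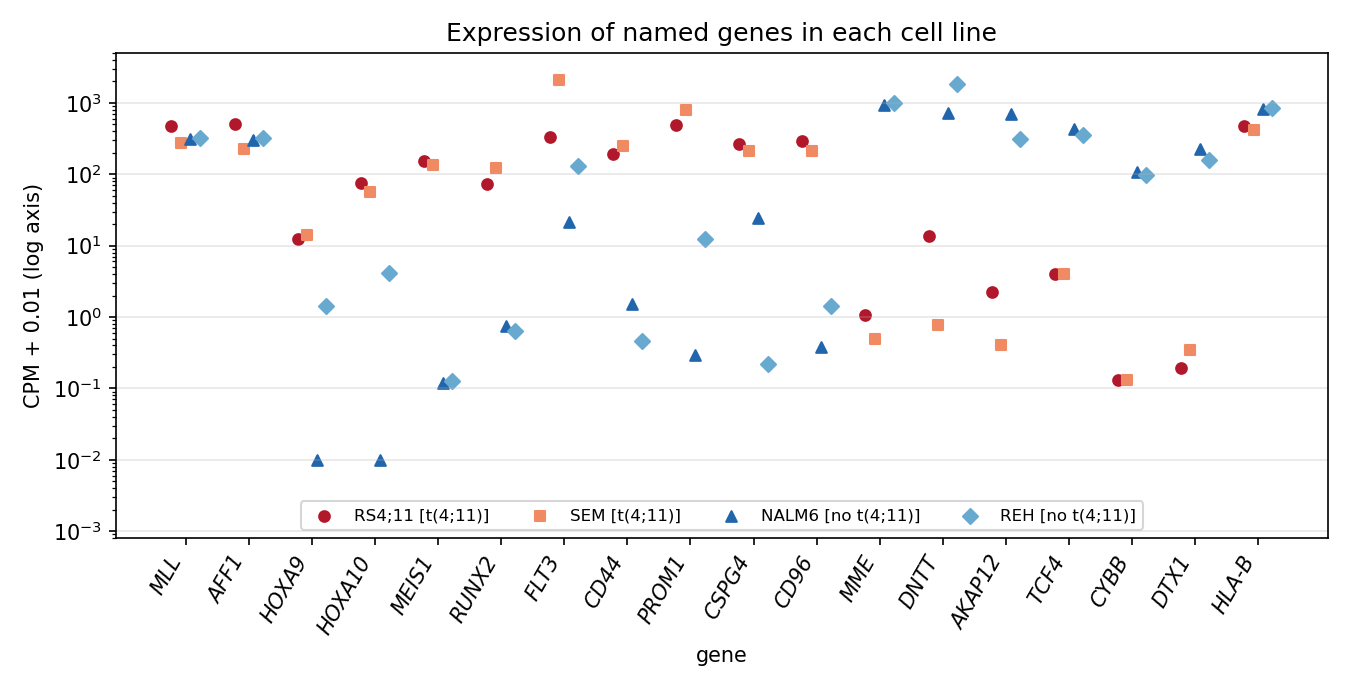
Level of named genes in each of the 4 lines, as CPM + 0.01 on a log axis, with 1 point per line, red and orange for the t(4;11) lines and blue for the controls. MEIS1 stood at 154 and 135 CPM in RS4;11 and SEM against 0.107 and 0.115 CPM in NALM6 and REH, while MLL stood between 272 and 478 CPM in all 4 lines.

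Known target genes of MLL fusion proteins outside the HOXA cluster rose as a group. Their median log2 fold change was 1.62 over 19 genes, and 14 of them were higher in both t(4;11) lines than in both controls. MEIS1 lies on chromosome 2 (66,662,532 to 66,799,891, hg19) and had a log2 fold change of 10.31 (SE 0.28, edgeR adjusted p = 0.0507). RUNX2, a Runt-family transcription factor, had 73.6 and 121 CPM in RS4;11 and SEM against 0.730 and 0.623 CPM in NALM6 and REH (log2 fold change 7.17, SE 0.43, edgeR adjusted p = 0.102). FLT3, a receptor tyrosine kinase, had 334 and 2120 CPM against 21.4 and 129 CPM. Its log2 fold change of 4.03 had an SE of 1.46 (edgeR adjusted p = 0.421) and was 2.17 without SEM. The authors' deposited DESeq table called 7 of the 19 genes higher, and 4 were called higher in their deposited Cuffdiff table, with none lower in either. Adjusted over the list alone, edgeR's quasi-likelihood test called 7 higher. The camera test gave an adjusted p of 9.01e-11 with its preset correlation of 0.01, a call lost with an estimated correlation (adjusted p = 0.318). The estimate was only 0.00239, and that version of the test called 0 of 5 simulated lists shifted 4-fold. The lost call therefore cannot decide whether the list changed.

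Known surface and expression markers of MLL-rearranged leukemia also rose as a group, with a median log2 fold change of 4.30 over 13 genes. MEIS1, RUNX2, FLT3 and PROM1 belong to both lists. PROM1, which encodes the stem cell antigen CD133, had 495 and 787 CPM in the t(4;11) lines against 0.279 CPM in NALM6 and 12.6 CPM in REH (log2 fold change 6.63, SE 2.06, edgeR adjusted p = 0.393; 11.14 without REH). CSPG4, the proteoglycan NG2 used to recognise MLL-rearranged blasts, had 266 and 210.03 CPM against 24.0 CPM in NALM6 and 0.208 CPM in REH (log2 fold change 4.30, SE 2.18, edgeR adjusted p = 0.524; 10.15 without NALM6). CD44 lies on chromosome 11 (35,160,417 to 35,253,949) and had a log2 fold change of 7.82 (SE 0.85, edgeR adjusted p = 0.274). FUT4, the fucosyltransferase that makes the CD15 antigen, had 148 ± 46.3 CPM against 28.2 ± 6.62 CPM (SD, n = 2 each). The authors' deposited DESeq table called 7 of the 13 genes higher, and 6 were called higher in their deposited Cuffdiff table. Adjusted over the list alone, edgeR's quasi-likelihood test called 5 higher. Camera's adjusted p was 6.66e-10 (adjusted p = 0.318 with an estimated correlation).

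The HOXA cluster on chromosome 7, which encodes homeobox transcription factors of early blood cells, was higher in the t(4;11) lines at HOXA7, HOXA9 and HOXA10. HOXA10 had 74.5 and 56.2 CPM in RS4;11 and SEM, 0 counts in NALM6 and 4.08 CPM in REH. HOXA9 had 12.6 and 13.9 CPM against 0 counts and 1.43 CPM. In Cuffdiff's FPKM, a length-scaled unit, the order was reversed in the t(4;11) group, at 51.7 for HOXA9 and 28.3 for HOXA10. Both genes share a locus there, so their levels relative to each other are uncertain. HOXA7 had 15.1 and 10.3 CPM against 0 counts and 0.300 CPM. These 3 genes were called higher in the authors' deposited DESeq table, and none of the 11 in their deposited Cuffdiff table. Adjusted over the list alone, edgeR's quasi-likelihood test called 0 of the 10 genes tested, and 1 had an unadjusted p under 0.05. Camera's adjusted p was 0.00844 for the list with a median log2 fold change of 1.40 (adjusted p = 0.722 with an estimated correlation). The camera call was also lost without RS4;11 (adjusted p = 0.0880 by limma's camera) and without NALM6 (0.728), and with the deposited Cuffdiff statistics (0.528). The cluster sits in a stretch of the short arm whose 159 expressed genes had a median log2 fold change of -1.02, a region singled out after its values were seen.

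**Figure D2:**
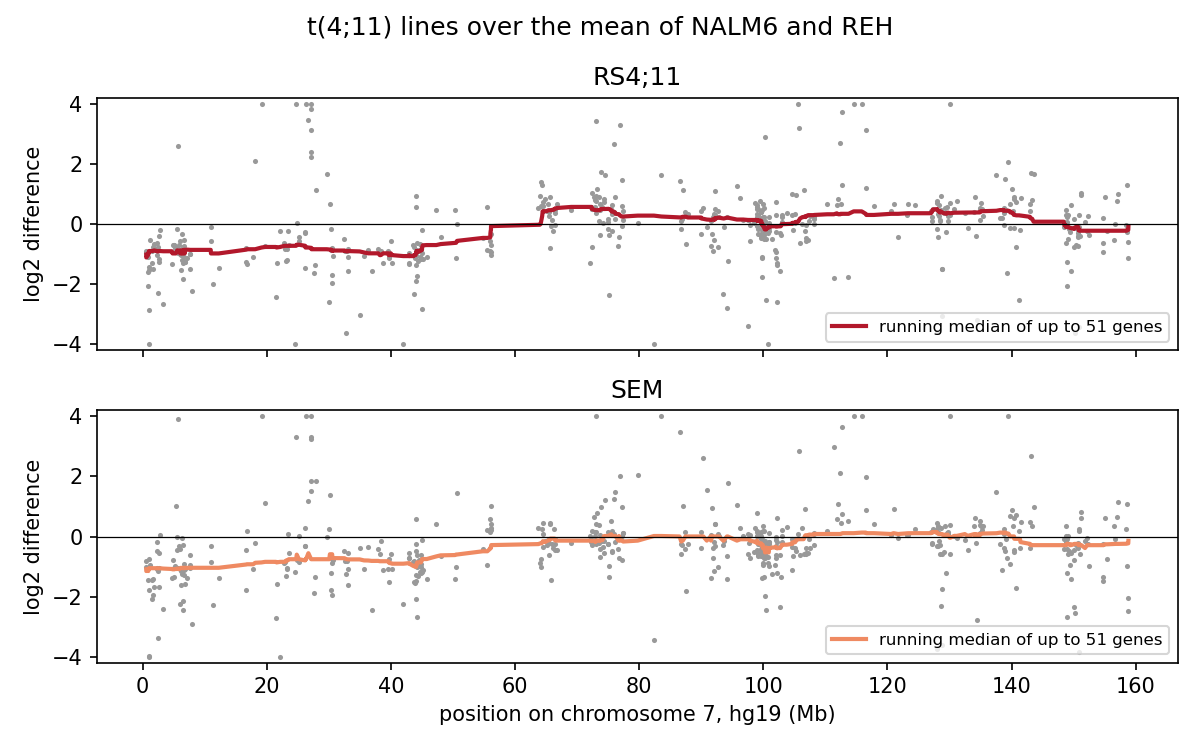
Log2 difference of RS4;11 (upper panel) and SEM (lower panel) from the mean of NALM6 and REH along chromosome 7 (hg19, Mb), with 1 grey point per gene and a running median as a line. Values beyond 4 are drawn at 4 in either direction, and the line runs below 0 over most of the short arm, where the 159 genes had a median log2 fold change of -1.02 against -0.01 over the 353 genes that follow.

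B-lineage and pre-B receptor genes had a median log2 fold change of -0.66 over 33 genes. Of these, 13 were lower in both t(4;11) lines than in both controls. MME lies on chromosome 3 (154,797,436 to 154,901,518) and had a log2 fold change of -10.26 (SE 0.60, edgeR adjusted p = 0.102). The log2 fold change of DNTT was -7.50 (SE 1.84, edgeR adjusted p = 0.355). RAG1, a subunit of the V(D)J recombinase, had 237 CPM in RS4;11 and 1.89 CPM in SEM against 670.4 and 3219.8 CPM. The B-cell master regulator PAX5 was not lower, with 287 and 431 CPM against 389 and 247 CPM; it was picked out after its values were seen. The authors' deposited DESeq table called 5 of the list's genes lower, and 9 were called lower in their deposited Cuffdiff table, with none higher in either. Adjusted over the list alone, edgeR's quasi-likelihood test called 1 lower. Camera's adjusted p was 0.00538 (adjusted p = 0.722 with an estimated correlation). Without SEM it was 0.108 and without NALM6 0.489.

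Antigen presentation genes had negative medians. The median log2 fold change was -0.75 over 13 MHC class I genes and -0.71 over 16 MHC class II genes, and 9 and 10 of these were lower in both t(4;11) lines than in both controls. HLA-B had 469 and 417 CPM in RS4;11 and SEM against 820.4 and 844 CPM in NALM6 and REH (log2 fold change -0.91, SE 0.17, edgeR adjusted p = 0.313). HLA-DQB1 went the other way, with 39.9 and 30.2 CPM against 2.19 and 4.72 CPM, and was called higher in the authors' deposited DESeq table. It was the only class II gene called in that table, and no class I gene was; their deposited Cuffdiff table called 1 class I gene lower and no class II gene. Adjusted over each list alone, edgeR's quasi-likelihood test called 0 class I genes and 1 class II gene higher and 2 lower. Camera's adjusted p was 0.00181 for class I (adjusted p = 0.638 with an estimated correlation) and 0.00538 for class II (adjusted p = 0.722 with an estimated correlation). Without NALM6 these became 0.0530 and 0.140, and with the deposited Cuffdiff statistics 0.0580 and 0.327. The loci given for HLA-B and HLA-DQB1 lie on alternative haplotype sequences of chromosome 6, near-identical copies that share reads, so the levels of these genes are uncertain.

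Ribosomal protein genes had a small positive median log2 fold change of 0.35 over 75 genes, and 44 of them were higher in both t(4;11) lines. RPL3 and RPL4, of the large subunit, had log2 fold changes of 0.18 (SE 0.25) and 0.20 (SE 0.24), and of 0.06 and 0.11 without NALM6; RPL3 had 0.11 without RS4;11 and 0.31 without REH. No ribosomal gene was called in either deposited table, and 0 were called by edgeR's quasi-likelihood test adjusted over the list alone, with 6 at an unadjusted p under 0.05. Camera's adjusted p was 7.97e-07 (adjusted p = 0.722 with an estimated correlation). Oxidative phosphorylation genes had a smaller median log2 fold change of 0.21 over 37 genes. NDUFA1 and NDUFA2, of respiratory complex I, had log2 fold changes of 0.17 (SE 0.30) and 0.08 (SE 0.20). The value for NDUFA1 turned to -0.10 without NALM6. Neither deposited table called an oxidative phosphorylation gene, and edgeR's quasi-likelihood test called 0 adjusted over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05. Camera's adjusted p was 0.0292 (adjusted p = 0.722 with an estimated correlation), and it was 0.164 without RS4;11, 0.0530 without NALM6, 0.101 without REH and 0.366 with the deposited Cuffdiff statistics.

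Camera called 8 of the 32 lists tested with its preset correlation and 0 with an estimated one. The estimated version also called 0 of 5 simulated lists shifted 4-fold, so its lost calls cannot decide for any list. Its estimates were 0.981 for HOXA, 0.354 for ribosomal and 0.296 for B-lineage genes, far above the preset 0.01. The preset calls of these lists cannot decide either, because the preset allows for little shared variation and the simulated genes were drawn independently. The estimates were below the preset 0.01 for MLL targets (0.00239), MLL markers (-0.0363) and MHC class I (-0.00340). The directional fry test called 0, with a smallest adjusted p of 0.0967. Its adjusted p was 0.500 for HOXA, 0.390 for ribosomal and 0.420 for B-lineage genes. The fry test for change in either direction called 13. Markers of other cell types were not called by camera, but that mixed fry test gave adjusted p-values of 0.0146 for T and NK cell genes and 0.0215 for erythroid and megakaryocyte genes (0.0962 for myeloid genes and 0.314 for stromal and epithelial genes). By camera the adjusted p was 0.375 for myeloid genes, 0.651 for T and NK cell genes, 0.904 for erythroid and megakaryocyte genes and 0.134 for stromal and epithelial genes. It was 0.0907 for the NOTCH pathway and for DUX4-rearranged leukemia markers, 0.109 for heat shock and stress genes, 0.210 for ETV6-RUNX1 leukemia markers and 0.305 for stem and progenitor genes. For signalling lists it was 0.331 for the WNT pathway, 0.379 for RAS and MAPK feedback genes, 0.379 for interferon-stimulated genes, 0.575 for cytokine and chemokine receptors and 0.951 for the TGF-beta and BMP pathway. Adhesion molecules had 0.347 and polycomb genes 0.391. Cell cycle genes had 0.578, G1 cyclins and CDK inhibitors 0.575 and the BCL2 family 0.921. Glucocorticoid response genes had 0.651, while MYC targets, glycolysis and the MLL partner and DOT1L complexes each had 0.705. DNA methyltransferases and TET enzymes had 0.740. The other HOX clusters, with 1 gene tested, and the pair of MLL and AFF1 were too few for a list test. Adjusted over the list alone, edgeR's quasi-likelihood test called 2 adhesion genes higher, 1 NOTCH gene lower, and 1 myeloid gene, 1 stem cell gene and 1 methylation gene higher.

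Single genes of the uncalled lists were called in the authors' deposited DESeq table. PROM1, CD44 and FUT4, given above, also belong to uncalled lists (stem and progenitor, adhesion and myeloid genes) and were called in both deposited tables. Among the further genes given in this paragraph only LIN28B was also called in the authors' deposited Cuffdiff table (q = 0.00418). The Cuffdiff q of the others lay between 0.0917 (DTX1) and 0.251 (TET1). The edgeR quasi-likelihood adjusted p lay between 0.102 (DTX1) and 0.412 (TNFRSF14 and RYK). LIN28B, an RNA-binding protein of fetal progenitors, had 21.5 and 15.8 CPM in RS4;11 and SEM and 0 counts in both controls. IL6R, the interleukin-6 receptor, had 9.53 and 6.51 CPM against 0.0644 and 0.196 CPM. DTX1, a NOTCH-induced ubiquitin ligase, had 0.182 and 0.336 CPM against 228 and 158 CPM (log2 fold change -9.56, SE 0.53). TNFRSF14, a receptor of the TNF family, had 0.142 and 2.57 CPM against 28.8 and 30.9 CPM. RYK, a WNT co-receptor, had 0.971 and 6.91 CPM against 29.3 and 43.2 CPM. TET1, which oxidises methylcytosine, had 3.18 and 0.764 CPM against 16.9 and 29.5 CPM.

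Among genes called by both deposited tables and counted in both groups, 26 were higher and 33 lower at a mean of at least 100 normalized counts, and the 10 largest changes each way were taken. CD96, an immunoglobulin-family receptor, led the higher ones at 253 ± 61.3 CPM against 0.898 ± 0.753 CPM (SD, n = 2 each; 282-fold). Its log2 fold change of 8.11 became 7.47 without NALM6 and 9.41 without REH. PROM1, CD44, CSPG4 and FUT4 were also among them. CLECL1, a C-type lectin-like gene, had 69.5 ± 8.65 CPM against 0.723 ± 0.435 CPM. IRAK3, an inhibitor of Toll-like receptor signalling, had 129 ± 72.1 CPM against 5.46 ± 6.94 CPM. SORD, sorbitol dehydrogenase, had 137 and 154 CPM in RS4;11 and SEM against 50.3 CPM in NALM6 and 0.104 CPM in REH. MSMO1, a sterol oxidase of cholesterol synthesis, was 5.57-fold higher, and PPP2R5C, a regulatory subunit of protein phosphatase 2A, 4.97-fold higher. PPP2R5C had the closest replicates of these, at 941 and 916 CPM against 171 and 202 CPM (log2 fold change 2.31, SE 0.19, edgeR adjusted p = 0.170).

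MME led the lower ones, followed by AKAP12, a scaffold of protein kinase A, at 1.31 ± 1.29 CPM against 503 ± 268 CPM (SD, n = 2 each). ITPR3, an inositol trisphosphate receptor, had 0.811 ± 0.541 CPM against 258 ± 59.5 CPM (log2 fold change -8.29, SE 0.73), and DNTT came after it. KDM5B, an H3K4 demethylase, had 2.06 ± 2.44 CPM against 205 ± 75.7 CPM. TCF4, an E-protein transcription factor, had 4.00 CPM in each t(4;11) line against 429 and 360 CPM (log2 fold change -6.62, SE 0.22, edgeR adjusted p = 0.0507). It lies on chromosome 18 (52,889,562 to 53,303,188). MYLK, myosin light chain kinase, and SERPINB9, an inhibitor of granzyme B, were 50.5-fold and 50.3-fold lower, and the log2 fold change of MYLK was -5.66, against -4.82 without NALM6 and -6.32 without SEM. DIP2C and MTSS1L completed the 10, at 94.6-fold and 94.1-fold lower. For MYLK the deposited tables differed in size, with a log2 fold change of -5.66 in the authors' deposited DESeq table and -4.75 in their deposited Cuffdiff table.

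The 10 genes with the smallest p by edgeR's quasi-likelihood test, leaving out the kinds of gene that are never named here, were added after the values were seen. Most were near 0 in one group. CYBB, the catalytic subunit of the phagocyte oxidase, had 6 and 4 counts in RS4;11 and SEM against 4947 and 8406 in NALM6 and REH (log2 fold change -9.68, SE 0.28, edgeR adjusted p = 0.0507). PTPRR, a receptor tyrosine phosphatase, had 5551 and 4638 counts against 1 count in each control (edgeR adjusted p = 0.0507). TWIST1, a basic helix-loop-helix factor, had 2868 and 3463 counts against 1 and 2. TMSB15A, an actin-binding thymosin, had 2114 and 1684 counts against 1 and 3, and PKIA, an inhibitor of protein kinase A, had 2181 and 1117 against 1 and 2. PRICKLE2, of planar cell polarity, had 1702 and 1485 counts against 1 and 3, and SPG20, which encodes spartin, had 3822 and 4171 against 1 and 4. MEIS1, TCF4 and DTX1 made up the rest.

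The second comparison asked how the choice of algorithm, DESeq or Cuffdiff, changes which genes are called. Both deposited tables found PROM1, CD44 and CSPG4 higher and MME and DNTT lower. MEIS1 was called only in the authors' deposited DESeq table (adjusted p = 1.69e-41) and not in their deposited Cuffdiff table (q = 0.303), although the log2 fold changes were 10.35 and 10.40. FLT3 was called only in the authors' deposited Cuffdiff table (q = 0.00418) and not in their deposited DESeq table (adjusted p = 1.00), with log2 fold changes of 4.03 and 4.04. Of the 14,127 genes tested in both, 287 were called in the DESeq table and 330 in the Cuffdiff table, and 81 in both. That was 28.2% of the DESeq calls and 24.5% of the Cuffdiff calls, where independent lists would share 6.70 genes (Fisher's exact test, one-sided, p = 3.80e-66). The shared genes were 42 higher and 39 lower, against 2.09 and 1.29 for independent lists (Fisher's exact test, one-sided, p = 1.26e-43 and 2.26e-48). No gene was called in opposite directions. Both tables came from the same 4 libraries, so their overlap measures agreement of methods.

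The genes called by 1 table alone differed in level. The authors' deposited DESeq table alone called 206, and the 5 with the smallest adjusted p were S100A10, PTPRR, MEIS1, CYBB and DST. S100A10, a calcium-binding partner of annexin, had 6116 and 4888 counts in RS4;11 and SEM against 0 and 3 in NALM6 and REH. DST, the cytoskeletal linker dystonin, had 3468 and 2580 counts against 6 and 5. The authors' deposited Cuffdiff table alone called 249. Its 5 with the highest counts among ties at the smallest q of 0.00418 were PAN3, RAG1, FLT3, EDEM1 and FLNA. PAN3, of the poly(A) nuclease complex, had 1957 CPM in RS4;11 and 5839.7 CPM in SEM against 222 and 316 CPM, and it lies beside FLT3 on chromosome 13 (28,710,980 to 28,869,475 and 28,577,411 to 28,674,729). EDEM1, of endoplasmic reticulum protein degradation, had 369.8 and 199 CPM against 697 and 1035 CPM. FLNA, filamin A, had 415 and 1337 CPM against 217 CPM in each control. The median mean normalized count was 840.3 for the genes called by DESeq alone, 348 for those called by Cuffdiff alone and 5039 for those called by both.

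**Figure D3:**
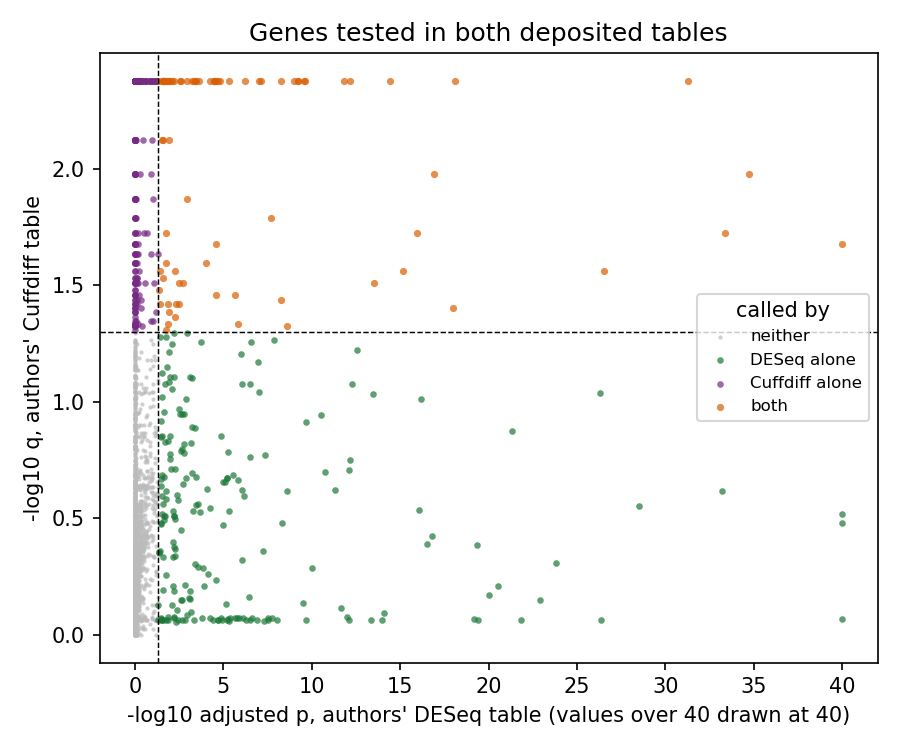
Each of the 14,127 genes tested in both deposited tables by its -log10 adjusted p in the authors' DESeq table (horizontal axis, values over 40 drawn at 40) and its -log10 q in their Cuffdiff table (vertical axis), with dashed lines at 0.05 and colours for the table that called it. The 81 genes called by both fill the upper right, and the Cuffdiff values end at the line of its smallest q, 0.00418.

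The fold changes behind the calls were nearly equal. Across 13,811 genes with finite values in both tables, Pearson's r of the log2 fold changes was 0.997 and Spearman's rho 0.992; the genes are not independent replicates. The sign was the same for 98.6% of genes, the median absolute difference was 0.00925 on the log2 scale, and 69 genes differed by more than 1. Cuffdiff's table gave no test to 8928 genes and marked 151 as having too little data, and 4952 entries of the DESeq table had no p because all 4 lines were at 0.

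The last comparison asked how far lines of a group resemble each other. RS4;11 and SEM were the most similar pair of lines, with a Spearman correlation of 0.929 across 13,844 genes. NALM6 and REH had 0.882, within the range of the 4 pairs from different groups (0.847 to 0.885), and these 2 controls differed over 4-fold in 1208 genes against 689 for RS4;11 and SEM. Comparing group means, 872 genes differed over 4-fold between the t(4;11) lines and the controls, against 547 and 513 for the other ways to divide the 4 lines into pairs. The groups did not overlap at 6593 genes (47.6%), where chance gives 33.3%. At an unadjusted p under 0.05 edgeR's quasi-likelihood test gave 1668 genes for the division by t(4;11) against 398 and 350 for the others. With 3 possible divisions the smallest share is 0.333, so no test of the division at 0.05 was possible.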

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

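The robust and the earlier (legacy) quasi-likelihood fits and the other divisions of the 4 lines were chosen after the data were seen; the other alternatives were planned. The planned change of pseudocount in the gene test was not run, since counts were given. No paired analysis was possible because the replicate numbers follow listing order only and the 4 lines are unrelated.

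The count of genes called by edgeR's quasi-likelihood test was 0, with 1668 at an unadjusted p under 0.05. It was 5 with no filter, 4 with at least 20 counts in 2 lines, 7 at an adjusted p under 0.1, 408 by edgeR's exact test and 1603 by DESeq2. It was 0 with RLE size factors, with the robust and legacy fits, at 0.01, with a 2-fold minimum and without any 1 line. In those last fits the lone line left in a group is assumed to vary like the other group, and between 795 (without SEM) and 2201 (without NALM6) genes had an unadjusted p under 0.05. The cause was not tested, and the simulated false calls given for the tools cannot settle it. The authors' DESeq calls stayed between 193 and 365 under 6 alternatives, against 288. Their 332 Cuffdiff calls fell to 190 at a q under 0.01, to 152 above the median expression and to 170 without genes at 0 in a group, and were 477 at 0.1. The overlap of 81 genes was 32 at 0.01 and 133 at 0.1, and 61 above the median expression and 70 by equal numbers of top genes. The r of fold changes, 0.99682, was 0.99737 above the median expression, 0.99666 below it and 0.99946 for genes called by either table. A stricter or looser threshold or fewer genes move these counts by construction; the cause of the shifts in r was not tested.

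The 8 lists called by camera became 0 with an estimated correlation, ranged from 5 (without NALM6) to 11 (without RS4;11) when 1 line was left out, and were between 7 and 10 under the other alternatives. With the deposited Cuffdiff statistics the HOXA, both MHC and the oxidative phosphorylation lists lost the call. The cause was not tested. The 872 genes over 4-fold apart were 322 above the median expression, 221 on log2(CPM + 10) and 2504 at 2-fold, which follows from the alternatives' construction. Among the named genes 3 changed sign, none of them called: NDUFA1 ranged from -0.10 (without NALM6) to 0.49 (without REH), MLL from -0.22 (without RS4;11) to 0.59 (without SEM) and AFF1 from -0.45 to 0.72 without the same lines. The log2 fold changes of PROM1, CSPG4, FLT3, IRAK3, SORD, HOXA7, HOXA9, HOXA10, TNFRSF14, RYK, RAG1, FLNA, RPL3 and RPL4 also moved by over 1.5 times on the log2 scale without 1 line. The cause of these shifts was not tested. Over the 54 named genes and the alternatives run gene by gene (RLE size factors, both filters, the exact test, DESeq2 and each line left out), 400 values kept their direction and stayed uncalled, and 83 kept their direction and passed the threshold. For the 8 called lists, 34 alternative values kept the call and 21 lost it with the same direction. Depth limits genes near 0: 3 counts are 0.0917 CPM in SEM, the library with the fewest counts, and 0.0346 CPM in REH.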

Other observations

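With an exception, the tests and genes in this part were chosen after the values were seen. The r of fold changes among genes called by either table was chosen before the data were examined, but its use as an argument here was not. HOXA expression differed between the controls. NALM6 held 0 counts for HOXA3, HOXA5 and HOXA13, whereas REH expressed HOXA3 and HOXA5 at levels near those of the t(4;11) lines. HOXA3 stood at 11.7 CPM in REH against 15.8 CPM in RS4;11 and 11.7 CPM in SEM, and HOXA5 at 7.24 CPM in REH against 14.3 and 7.24 CPM. HOXA13, the last gene of the cluster, had 8.37 CPM in REH and at most 4 counts in each other line, and HOTTIP, a noncoding RNA beside it, had 1.63 CPM in REH.

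Each line also had genes far above the other lines. NALM6 had AGAP1 at 388 CPM (23.0 CPM in REH and 11.5 CPM in SEM), PTPRM at 102 CPM (4.66 CPM in REH) and the lectin receptor CLEC12A at 30.1 CPM. These are 3 of the 6 markers listed for DUX4-rearranged leukemia. Of the others ERG was lower in NALM6 (133 CPM) than in REH (489 CPM) and RS4;11 (215 CPM), DUX4 had 0 counts in every line and CD2 at most 2. The count of DUX4 cannot show its absence, because the handling of reads that match several places is not given. NALM6 also had the growth factor receptor PDGFRA at 464 CPM; PDGFRA and CLEC12A had at most 11 counts in any other line. REH had the RNA-binding protein IGF2BP1 at 285 CPM, ARHGAP29 at 78.0 CPM, CLIC5 at 67.5 CPM, BIRC7 at 34.2 CPM, DSC3 at 28.2 CPM and the erythropoietin receptor EPOR at 20.8 CPM. These 6 of the 8 markers listed for ETV6-RUNX1 leukemia lay over 4-fold above every other line, unlike TCFL5 (49.9 CPM in REH and 44.5 CPM in NALM6) and DSC2 (8.17 CPM in REH and 6.14 CPM in SEM). REH also held myeloperoxidase (MPO, 33.2 CPM) and MECOM (13.0 CPM), with at most 18 counts of either in another line. SEM had the myeloid factor CEBPA at 163 CPM against 9.87 CPM in RS4;11 and 0 counts in both controls, the aminopeptidase ANPEP (CD13) at 200.2 CPM, the T-lineage factor TCF7 at 122 CPM and N-cadherin (CDH2) at 47.2 CPM. Genes at 10 CPM or more in 1 line and at most 3 counts in each other line numbered 37 in SEM, 32 in REH, 9 in NALM6 and 1 in RS4;11.

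DESeq and Cuffdiff called mostly different genes from nearly the same fold changes where these were finite. Different fold changes behind the tables are argued against by the r of 0.999 among the 375 finite genes called by either. That r does not cover genes at 0 in the lower group: 141 of the 249 called by Cuffdiff alone (56.6%) and 1 of the 206 called by DESeq alone (0.485%). Fold changes show neither the levels nor their spread, so whether different expression values lay behind the tables was not tested. A candidate explanation is that Cuffdiff withholds calls from genes near but not at 0 in a group. Among genes at 20 CPM or more in both lines of 1 group and at least 16-fold apart, it called 0 of 31 (0%) with 1 to 20 counts in the lower group, where DESeq called 27, and it called 30.3% at 21 to 100 counts, 56.3% above that and 3 of only 3 at 0; at any level, it called 160 of the 316 tested genes with a lower group at 0, and DESeq called 20. The lines of the higher group differed over 8-fold in 52.6% of the genes called by Cuffdiff alone, 0% of those called by DESeq alone and 10.3% of those called by neither. A preference of Cuffdiff for genes carried by 1 line is argued against only among genes at least 16-fold apart or at 0 in a group. There it called 18.1% of the 634 whose lines differed so and 20.4% of the 495 others. With the lower group at 0 the shares were 49.5% and 52.6%, and with it above 0 they were 3.69% and 10.6%. Fold and level were not matched within these sets, and genes less far apart are not covered. DESeq called 0 of the 634 and 182 of the 495, and the cause of that difference was not tested.

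Most of the short arm of chromosome 7 was lower in the t(4;11) lines, from 588,834 to 50,518,088 in hg19. The end of this stretch was set from the same fold changes, so the shares of its genes given in this paragraph describe it and are not separate support. A few strong genes do not account for the shift: 76.7% of the 159 genes were lower in both t(4;11) lines than in both controls, against 22.1% of genes on other chromosomes. GC content does not either, since the median log2 fold change of the 139 genes with a known GC content was -1.05 before and -1.03 after removing its trend, which moved the 1893 genes lowest in GC from 0.12 to 0.00 and the 1893 highest from -0.09 to -0.01. A copy number difference of a segment is a candidate explanation. Bounded from RS4;11 over NALM6, the region had a median of -0.91 in SEM over REH, the pair with no shared library. That lay under the lowest of 6295 overlapping runs of neighbouring genes on other chromosomes (-0.69), against -0.34 over the rest of chromosome 7. The 3 other pairings gave -0.89 to -0.95, with -0.01 to 0.36 over the rest. Chromosome 7 was itself picked from the contrast of all the lines, so no pair was independent of that choice. Among the chromosomes its break ranked 2 from RS4;11 over NALM6, and between 1 (SEM over NALM6) and 3 (SEM over REH) in all. The boundary moved with the pair. It fell after CHCHD2 (end 56,174,187) for RS4;11 over NALM6 and after TNS3 (end 47,621,742) for RS4;11 over REH. For both pairs with SEM it fell after FIGNL1 (end 50,518,088). Over the 10 genes from there to CHCHD2, RS4;11 had a median of -0.63 over the control mean, with 2 genes above it. SEM had 0.26, with 8 above it. RNA alone leaves open whether the lines share a boundary and whether the t(4;11) lines hold fewer copies or the controls more. The region bears on the division of the groups. By edgeR 76 of the 159 genes (47.8%) were lower at an unadjusted p under 0.05, against 5.39% of genes on other chromosomes. They were a small part of the 1668 genes at such a p.

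Genes of 9p21 (chromosome 9, 20,344,968 to 22,452,472) were counted in SEM and almost nowhere else. The 32 genes of the interval summed to 11,718 counts in SEM, 1 in RS4;11, 4 in NALM6 and 0 in REH; MTAP had 4045 counts in SEM, CDKN2A, which encodes p16INK4a and p14ARF, 3303, and KLHL9 2392. Too little depth is argued against because 4 of the genes had over 1000 counts in SEM, the library with the fewest counts. Loss of the locus in the other lines is a candidate explanation: the 6 genes above 5 CPM in SEM had at most 2 counts in any other line, while 26 of 30 values of the 10 flanking genes lay within 4-fold of SEM. Silencing without loss was not tested.

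Further shifts along chromosomes are given as values. RS4;11 against the median of the other lines had a median log2 difference of -0.93 on chromosome 8 up to HGSNAT (end 43,057,970) and 0.61 from KIAA0146 (start 48,173,489) on. REH had -0.71 on chromosome 3 up to KCTD6 (end 58,488,087). SEM had a median of -0.84 over the 126 genes of chromosome 13 that follow EXOSC8 (end 37,633,850) and -0.19 over the 60 up to it, the part that holds FLT3 and PAN3.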
